A study of Mus musculus with 12 samples.

How the data were processed

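RNA from 12 samples, 2 in each of 6 groups, was hybridised to 1-colour mouse arrays (Agilent SurePrint G3, Cy3). Per the labels, the RNA was cytoplasmic and was labelled by a low-input amplification. The scanner files deposited by the authors come from Agilent Feature Extraction 10.7.3.1 and hold an intensity per spot. The processed signal is a background-corrected intensity per the file headers, and the mean and background signals are raw intensity. The other columns used, per the file headers, are flags for saturation and for a spot well above background. The deposited table of values is, per the labels, on a log2 scale after quantile normalization with limma (no version is given), with values from 1.47 to 18.56. Checked against the scanner values, its Spearman correlation across features was 1 on every array. It has 12 sample columns, of which 0 were left unused. Saturated spots numbered 0 and flagged spots 106 to 220 per array. The number of arrays limits the precision.

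The main values were log2 processed signal less each array's 75th percentile. A probe was kept when well above background on both arrays of at least 1 group (33037 of 55681 non-control probes, 22608 of them on all 12 arrays). Control spots and spots flagged as outliers were left out, and spots of 1 probe were averaged. The probe with the highest mean stood for its gene, giving 23837 genes, 15147 with a symbol and 6263 with several kept probes. Probes were named by accession (26582), by the name in the file (26005), by symbol (2602) or by synonym (492). The file coordinates are on mm9, and the gene table at hand, on another build, gave names only. A gene was below background in a group when none of its probes was well above background on either array. A fold written "at least" then compares the mean of the other group, well above background on both arrays, with the signal raised to the floor where it lay lower. The floor is each array's lowest signal well above background. A list median with genes at their bound uses these values, and 0 for genes below background in both groups.

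A linear model with a mean per group was fitted over all 12 arrays with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8), with empirical Bayes moderation (6 residual and 1.74 prior degrees of freedom). The 10 contrasts were TKO against WT in each cell type, Flk1+ and ntTS against ES cells in each genotype, and the differences between TKO effects. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 and a log2 change of at least 1. The 26 gene lists were 24 written by hand, the X-linked genes by chromosome, and a rule for endogenous retrovirus names in the array annotation. They were tested with camera at a preset correlation of 0.01, adjusted over lists within a contrast, and again with an estimated correlation. X-linked shares were tested with Fisher's exact test, 2-sided, against all genes tested with a chromosome, and overlaps were set beside the number that independence gives. The lists, contrasts, thresholds, alternatives and the naming rule were chosen before the data were examined.

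Genes named in the text were chosen by a rule, from genes with a symbol (accessions, predicted genes and Riken clone names left out). For each TKO contrast it takes Dnmt1, Dnmt3a and Dnmt3b, the 7 largest rises and falls among genes above background in both groups, the 5 largest bounds, up to 4 members per list by adjusted p, and Xist, Elf5, Pou5f1, Cdx2 and Kdr. For other contrasts it takes 4 rises, 4 falls and up to 4 members per list. The stromal genes Col1a1 and Col3a1, and Col1a2, Sparc, Postn and Dcn in Flk1+ cells, fall outside the rule. They were chosen after their values were seen.

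The alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization, median centring, no filter, only probes well above background on all 12 arrays, and the authors' value table. Others were only the arrays compared, slide as a block, a replicate block, leaving out each array in turn, no minimum fold, the mean of a gene's probes, moderation with trend and robust, and the estimated correlation. Scan run as a block was added after the data were seen. The labels do not pair the arrays by replicate number, but in ES and Flk1+ cells replicates 1 and 2 lay on slides 1 and 2, so a replicate block is there a slide block. Across genes, which are not independent replicates, the difference between replicates in WT correlated with that in TKO at r = 0.11, 0.10 and 0.03 in ES, Flk1+ and ntTS cells. The fit was tested on data simulated with the real spreads, with known changes added to the WT means for TKO. In ES, Flk1+ and ntTS cells, 77.6, 74.6 and 71.6% of log2 1.5 changes and 97, 97 and 100% of log2 4 changes were recovered. False calls numbered 3, 6 and 5 among 23837 genes, and 0 of 100 unchanged lists were called in each. Correlation between genes was not simulated, so co-regulated lists were not tested.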

Results

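Transcript levels were measured on 12 one-colour arrays, 2 for each of 6 groups: wild-type (WT) cells and cells lacking all 3 DNA methyltransferases, Dnmt1, Dnmt3a and Dnmt3b (TKO), as embryonic stem (ES) cells, as mesoderm cells sorted for the receptor Flk1 (Flk1+), and as trophoblast stem cells derived from nuclear-transfer embryos (ntTS). Flk1+ cells had been differentiated from ES cells on a stromal cell layer, and ntTS cells had been sorted away from embryonic fibroblast feeder cells by green fluorescence. Each array held 59305 non-control spots, of which 49.2 to 57.2% were well above background. The arrays of a group correlated at r = 0.990 to 0.995 across genes, which are not independent replicates. WT and TKO cells came from different lines in every cell type. WT ES cells were grown in serum replacement with adrenocorticotrophic hormone and TKO ES cells in fetal calf serum, so medium and genotype cannot be separated in ES cells; the labels give 1 medium for both genotypes in the other cell types. The labels do not say whether the arrays of a group were separate cultures, so p-values measure only the spread between these samples. Gene values are log2 fold changes ± standard error from 2 arrays per group, and "at least" marks a fold computed against the background floor because 1 group lay below background. Counts of list members adjusted over the list alone are given where they differ. The median change over all genes was -0.13 on the log2 scale in Flk1+ cells, against -0.03 in ES and -0.05 in ntTS cells, and changes are relative to each array's 75th percentile. In Flk1+ cells that median was -0.06 with quantile normalization, -0.03 with normexp background correction and -0.11 with median centring.

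The probe signals of the deleted genes were lower in every TKO sample than in every WT sample. Dnmt1, the maintenance methyltransferase, lay between 1.84 and 2.39 on the 6 WT arrays and between -2.34 and -1.58 on the 6 TKO arrays (log2 signal relative to the 75th percentile). Dnmt3a, a de novo methyltransferase, lay between 0.15 and 0.94 on WT arrays and was well above background on 0 of 6 TKO arrays. Dnmt3b, the other de novo enzyme, lay between 5.69 and 7.19 on WT arrays and between 1.91 and 2.89 on TKO arrays, well above background on all 6 of the latter. Dnmt1 fell by 4.62, 4.32 and 3.56 on the log2 scale in ES, Flk1+ and ntTS cells (SE 0.11, adjusted p = 3.6e-06, 1.4e-07 and 4.2e-07). Dnmt3b fell by 4.72, 3.63 and 4.30 (SE 0.14, adjusted p = 3.7e-06, 1.3e-06 and 6e-07), and Dnmt3a was at least 41.2-fold (adjusted p = 3e-05), at least 39.4-fold (adjusted p = 2e-05) and at least 41.2-fold (adjusted p = 2.7e-05) lower. The probes used lay on the mm9 build at chromosome 9, 20711973 to 20712341 for Dnmt1, chromosome 12, 3914320 to 3914379 for Dnmt3a and chromosome 2, 153513403 to 153513462 for Dnmt3b. The labels do not give the deleted parts of the genes, so these probes cannot be placed inside or outside the deletions. A lower signal need not mean a lower level of the whole transcript.

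**Figure D1:**
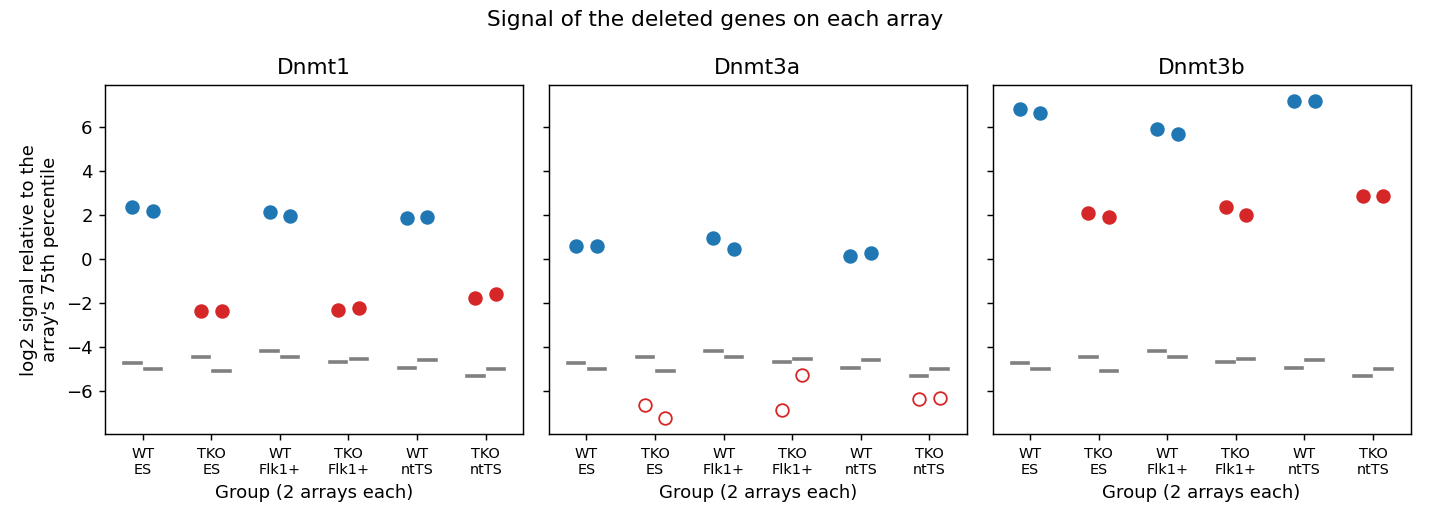
Signal of Dnmt1, Dnmt3a and Dnmt3b on each of the 12 arrays (log2, relative to the array's 75th percentile), with the background floor of each array as a grey dash. Filled points are well above background and open points are not: Dnmt3a is open on all 6 TKO arrays, while Dnmt3b stays between 1.91 and 2.89 there.

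The comparison of TKO with WT ES cells asks what changes in undifferentiated cells without the 3 methyltransferases. Primitive endoderm genes rose: Foxa1, a transcription factor of the endoderm (2.86 ± 0.11, adjusted p = 7e-06), and the basement membrane genes Lamb1 (1.66 ± 0.08, adjusted p = 1.4e-05) and Col4a1 (1.88 ± 0.09, adjusted p = 1.6e-05). H19, a maternally expressed imprinted RNA, rose by 4.04 ± 0.18, adjusted p = 1.3e-05, and Rhox4a, an X-linked homeobox gene, by 3.96 ± 0.18, adjusted p = 1.3e-05. Enpp2, which encodes the secreted enzyme autotaxin (5.12 ± 0.27, adjusted p = 1.9e-05), and Coch (4.08 ± 0.34, adjusted p = 0.00011) rose. Tbx21, a T-box transcription factor (3.87 ± 0.21, adjusted p = 1.9e-05), and Id2, an inhibitor of differentiation factors (3.87 ± 0.22, adjusted p = 2.3e-05), also rose. Evx1, a homeobox gene of the primitive streak, and Prom2, a membrane glycoprotein gene, were below background in WT and at least 14.8-fold (adjusted p = 5.6e-05) and at least 13.1-fold (adjusted p = 1.8e-05) higher in TKO ES cells. Stra8, a gene required for meiotic entry (-4.61 ± 0.20, adjusted p = 1e-05), and the homeobox gene Nkx6-3 (-4.97 ± 0.74, adjusted p = 0.0016) fell. The histidine-degrading enzyme gene Hal (-3.75 ± 0.21, adjusted p = 2e-05) and the collagen gene Col1a2 (-3.95 ± 0.33, adjusted p = 0.00011) fell too. The pluripotency factor gene Pou5f1 was not called (0.22 ± 0.26, adjusted p = 0.59). Nor was Kdr, which encodes Flk1 (-0.06 ± 0.10, adjusted p = 0.7), or the trophoblast regulator genes Cdx2 (0.45 ± 0.34, adjusted p = 0.37) and Elf5, which was below background in both genotypes. In all, 2811 of 23837 genes were called, 1591 higher and 1220 lower, and 252 of the higher genes were below background in WT. With no minimum fold 3478 genes were higher and 4084 lower.

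Grouped by gene list, primitive endoderm genes had the smallest p of the 26 lists: 15 of 21 rose and 1 fell (16 and 1 adjusted over the list alone). The primitive endoderm median was 1.67 (adjusted p = 6.2e-10, and adjusted p = 0.0086 with an estimated correlation). Primitive endoderm medians within slides 1 and 2 were 1.61 and 1.77. Among X-linked MAGE, Xlr and related genes, silent in most somatic cells, 14 of 28 rose and 1 fell, with Magea5 at least 12.2-fold (adjusted p = 1.7e-05) higher. The MAGE and Xlr median was 1.70 (adjusted p = 2.4e-05, and adjusted p = 0.12 with an estimated correlation). MAGE and Xlr medians within slides 1 and 2 were 1.73 and 1.67, and 1.64 with genes at their bound. In the Rhox homeobox cluster 7 of 18 rose and 0 fell. The Rhox median was 0.54 (adjusted p = 0.00058, and adjusted p = 0.2 with an estimated correlation). Rhox medians within slides 1 and 2 were 0.37 and 0.82. The Rhox and MAGE calls were lost over probes well above background on all 12 arrays, at 1.16 (adjusted p = 0.181) and 0.38 (adjusted p = 0.22). Imprinted genes next to a maternally methylated region also shifted: 6 of 22 rose and 1 fell (7 and 1 adjusted over the list alone), among them the rises of Magel2 (3.01 ± 0.09, adjusted p = 3.6e-06) and the zinc-finger gene Plagl1 (2.86 ± 0.19, adjusted p = 4.6e-05) and the fall of Peg12 (-1.92 ± 0.13, adjusted p = 5.3e-05). The maternal-region imprinted median was 0.73 (adjusted p = 5.6e-05, and adjusted p = 0.13 with an estimated correlation). Maternal-region imprinted medians within slides 1 and 2 were 0.73 and 0.66. H19, Mirg and Meg3, imprinted RNAs active on the unmethylated maternal allele, all rose. The H19, Mirg and Meg3 median was 1.66 (adjusted p = 0.00044, and adjusted p = 0.13 with an estimated correlation). H19, Mirg and Meg3 medians within slides 1 and 2 were 1.84 and 1.48. On the X chromosome 121 of 988 rose and 35 fell. The X-linked median was 0.04 (adjusted p = 0.042, and adjusted p = 0.028 with an estimated correlation). X-linked medians within slides 1 and 2 were 0.06 and 0.02, and 0.01 with genes at their bound. The X call was lost without WT ES replicate 1 (adjusted p = 0.0584), without TKO ES replicate 2 (median 0.074, adjusted p = 0.0674) and with slide as a block (adjusted p = 0.0527). Its adjusted p ran from 0.0527 to 0.254 (medians -0.013 to 0.074) over 10 alternatives that ended the call, and its median turned to -0.013 (adjusted p = 0.254) over probes well above background on all 12 arrays (here and below without counting the estimated correlation).

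Lists of differentiated lineages had medians under 1 log2 unit. Among early mesoderm genes, 11 of 29 rose and 3 fell. The early mesoderm median was 0.33 (adjusted p = 0.029, and adjusted p = 0.13 with an estimated correlation). Early mesoderm medians within slides 1 and 2 were 0.85 and 0.32, and 0.04 with genes at their bound. Among blood and endothelial precursor genes, 10 of 27 rose and 2 fell, with Etv2, a regulator of the hemangioblast (1.78 ± 0.15, adjusted p = 0.0001), among the rises. The blood and endothelial median was 0.53 (adjusted p = 0.002, and adjusted p = 0.38 with an estimated correlation). Blood and endothelial medians within slides 1 and 2 were 0.54 and 0.30, and 0.23 with genes at their bound. Primitive red cell genes included Epor, the erythropoietin receptor gene (1.96 ± 0.23, adjusted p = 0.00053), and 3 of 10 rose and 0 fell. The red cell median was 0.50 (adjusted p = 0.011, and adjusted p = 0.2 with an estimated correlation). Red cell medians within slides 1 and 2 were 0.32 and 0.75, and 0.24 with genes at their bound. Of the trophoblast stem cell genes, 5 of 20 rose and 0 fell, with Gata3 at 2.30 ± 0.16, adjusted p = 4.9e-05 and the keratin gene Krt8 at 1.40 ± 0.11, adjusted p = 8.9e-05. The trophoblast stem cell median was 0.57 (adjusted p = 0.036, and adjusted p = 0.3 with an estimated correlation). Trophoblast stem cell medians within slides 1 and 2 were 0.60 and 0.54, and 0.51 with genes at their bound. That call was lost without WT ES replicate 1 (adjusted p = 0.0509, and 0.0509 to 0.254 (medians 0.14 to 0.61) over 4 alternatives that ended it). With quantile normalization the early mesoderm and trophoblast lists were no longer called (adjusted p = 0.0572 and 0.0572), and with normexp the early mesoderm and red cell lists were not (adjusted p = 0.122 and 0.057). Over all alternatives that ended these calls, the adjusted p ran from 0.0572 to 0.352 (medians 0.041 to 0.33) over 6 for early mesoderm and from 0.057 to 0.176 (medians 0.12 to 0.44) over 2 for red cell genes.

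Metabolic and stress lists shifted by less than 1 log2 unit. For sterol synthesis genes, 0 of 24 rose and 2 fell, with Msmo1, a sterol oxidase gene, at -1.28 ± 0.09, adjusted p = 4.4e-05, and Hmgcs1, an early enzyme gene of the pathway, at -0.81 ± 0.10, adjusted p = 0.00058 so not called. The sterol median was -0.63 (adjusted p = 1e-06, and adjusted p = 0.22 with an estimated correlation). Sterol medians within slides 1 and 2 were -0.63 and -0.62. For p53 target genes, 0 of 22 rose and 4 fell, including the cell death gene Pmaip1 (-1.48 ± 0.13, adjusted p = 0.00013) and the cell cycle inhibitor gene Cdkn1a (-1.16 ± 0.14, adjusted p = 0.00064). The p53 target median was -0.57 (adjusted p = 9.3e-05, and adjusted p = 0.22 with an estimated correlation). P53 target medians within slides 1 and 2 were -0.55 and -0.53. For hypoxia and glycolysis genes, 5 of 20 rose and 2 fell, with the glycolysis regulator gene Pfkfb3 at 1.20 ± 0.08, adjusted p = 4.3e-05. The hypoxia median was 0.51 (adjusted p = 0.012, or 0.13 with an estimated correlation), and 0.57 and 0.45 within slides 1 and 2. For the methylation machinery, 0 of 15 rose and 4 fell. The methylation machinery median was -0.43 (adjusted p = 0.018, and adjusted p = 0.13 with an estimated correlation). Methylation machinery medians within slides 1 and 2 were -0.37 and -0.46. The machinery call was lost with scan run as a block (adjusted p = 0.0547) and over the 4 ES arrays alone (adjusted p = 0.0771), with values of 0.0547 to 0.0771 (medians -0.43 to -0.40) over 3 alternatives that ended it. Germline genes were not called (10 rose and 6 fell of 50, median 0.39, adjusted p = 0.058), although Asz1, a gene of the piRNA pathway, was at least 6.93-fold (adjusted p = 9.2e-06) higher and the RNA helicase gene D1Pas1 fell by 2.68 on the log2 scale. The germline list passed without WT ES replicate 2, TKO ES replicate 1 or either WT ntTS array (adjusted p = 0.0446, 0.0345 and 0.0474, or 0.0345 to 0.0474 (medians 0.39 to 0.44) over 4 alternatives).

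Lists not called in ES cells were imprinted genes repressed when the control region is unmethylated (3 rose and 4 fell of 21, median -0.14, adjusted p = 0.5), pluripotency genes (0 rose and 1 fell of 26, median -0.23, adjusted p = 0.43), 2-cell stage genes (2 rose and 1 fell of 17, median 0.33, adjusted p = 0.29) and interferon-stimulated genes (4 rose and 0 fell of 27, median 0.10, adjusted p = 0.29). The same held for neural precursor genes (7 rose and 3 fell of 14, median 0.97, adjusted p = 0.32) and serum response genes (3 rose and 1 fell of 21, median 0.16, adjusted p = 0.35). Median, mean and test differed in sign for differentiated trophoblast genes (1 rose and 1 fell of 14, median -0.17, mean -0.10, test direction up, adjusted p = 0.78), cell division genes (0 rose and 0 fell of 25, median -0.02, mean 0.01, test direction up, adjusted p = 0.47) and HOX genes (5 rose and 9 fell of 27, median 0.11, mean -0.49, test direction down, adjusted p = 0.51). They also differed for the endogenous retrovirus rule (2 rose and 0 fell of 12, median -0.07, mean 0.28, test direction up, adjusted p = 0.36), of whose 12 measured members 11 are host genes with a symbol. Fibroblast and stromal genes were not called either (7 rose and 6 fell of 29, median 0.09, mean 0.00, test direction up, adjusted p = 0.61), yet Col1a1 (-2.88 ± 0.29), Col1a2 (-3.95 ± 0.33) and Col3a1 (-3.36 ± 0.60) fell in the same TKO ES samples in which the primitive endoderm collagen Col4a1 rose.

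Of 14 lists called in ES cells, 13 kept their call with slide as a block and 11 with scan run as a block. By gene, 2805 genes were called with slide as a block and 2327 with scan run as a block.

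The comparison of TKO with WT Flk1+ cells asks what changes in TKO cells once they enter the mesoderm. Germ cell genes rose: Tex19.1, which acts against retrotransposons in germ cells (7.02 ± 0.10, adjusted p = 2.1e-08), the testis tubulin genes Tuba3a (8.67 ± 0.22, adjusted p = 1.4e-07) and Tuba3b (8.11 ± 0.14, adjusted p = 3.9e-08), and Dazl, an RNA-binding protein gene of germ cells, at least 46.1-fold (adjusted p = 5.1e-08) higher. On the X chromosome, Rhox2h rose by 9.004 ± 0.19, adjusted p = 6.8e-08, and Rhox2e, Xlr3b and Ezhip, an inhibitor of Polycomb, were below background in WT and at least 504-fold (adjusted p = 7.3e-08), at least 455-fold (adjusted p = 4.7e-08) and at least 437-fold (adjusted p = 4.3e-08) higher in TKO. Rpl39l, a ribosomal protein gene of the testis, was at least 275-fold (adjusted p = 1.2e-05) higher. The imprinted growth factor gene Igf2 (-6.68 ± 0.33, adjusted p = 4.3e-06) and the imprinted adaptor gene Grb10 (-5.75 ± 0.17, adjusted p = 3.5e-07) fell, as did Cabp5, a calcium-binding protein gene (-6.45 ± 0.36, adjusted p = 7.7e-06), and Shc4 (-6.28 ± 0.33, adjusted p = 5.4e-06). Chil3, a chitinase-like gene (7.97 ± 0.25, adjusted p = 4e-07), and Mc3r, a melanocortin receptor gene (6.21 ± 0.18, adjusted p = 2.6e-07), rose. Kdr, whose product Flk1 was the sorting marker, was not called (-0.84 ± 0.10, adjusted p = 0.0003), nor was Pou5f1 (0.07 ± 0.26, adjusted p = 0.85), and Elf5 was below background in both genotypes. Kdr passed the fold threshold with the mean of its probes (log2 -1.02 to -0.78 over its alternatives). Cdx2 fell (-1.78 ± 0.34, adjusted p = 0.0035), a call lost with scan run as a block (adjusted p = 0.094, within 0.00067 to 0.094 over its alternatives) and with a replicate block. In all, 3903 of 23837 genes were called, 2376 higher and 1527 lower, and 780 of the higher genes were below background in WT. The balance turned with no minimum fold, at 5210 higher and 6661 lower.

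Germline genes as a list rose: 38 of 50 rose and 2 fell, with the meiotic gene Tex11 at least 15.7-fold (adjusted p = 6.8e-08) higher. The germline median was 3.74 (adjusted p = 2.9e-16, and adjusted p = 0.013 with an estimated correlation). Germline medians within slides 1 and 2 were 3.54 and 3.74, and 2.13 with genes at their bound. X-linked MAGE, Xlr and related genes rose as well: 23 of 28 rose and 0 fell, with Xlr5b at least 110.3-fold (adjusted p = 1.1e-08) higher. The MAGE and Xlr median was 4.44 (adjusted p = 5.7e-13, and adjusted p = 0.013 with an estimated correlation). MAGE and Xlr medians within slides 1 and 2 were 4.33 and 4.55, and 2.95 with genes at their bound. In the Rhox homeobox cluster 14 of 18 rose and 0 fell, with Rhox5 at 5.76 ± 0.13, adjusted p = 8.3e-08. The Rhox median was 4.41 (adjusted p = 2.5e-09, and adjusted p = 0.052 with an estimated correlation). Rhox medians within slides 1 and 2 were 4.71 and 4.35, and 4.34 with genes at their bound. Of 2-cell stage genes, 8 of 17 rose and 0 fell (9 and 0 adjusted over the list alone). The 2-cell stage median was 1.80 (adjusted p = 0.0087, and adjusted p = 0.39 with an estimated correlation). 2-cell stage medians within slides 1 and 2 were 0.84 and 2.75, and 1.61 with genes at their bound. Over probes well above background on all 12 arrays, the MAGE and 2-cell medians turned to -0.25 and -0.18 (adjusted p = 0.873 and 0.908), a filter that removes genes below background in WT.

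Imprinted genes moved in both directions in Flk1+ cells. Among those repressed when the control region is unmethylated, 0 of 21 rose and 9 fell, with the growth inhibitor gene Cdkn1c at -3.83 ± 0.13, adjusted p = 6.8e-07 and the Igf2 receptor gene Igf2r at -2.18 ± 0.16, adjusted p = 3e-05. The repressed imprinted median was -0.55 (adjusted p = 0.0038, and adjusted p = 0.094 with an estimated correlation). Repressed imprinted medians within slides 1 and 2 were -0.72 and -0.35, and -0.32 with genes at their bound. That call was lost over probes well above background on all 12 arrays, at -0.55 (adjusted p = 0.0754). Among those next to a maternally methylated region, 7 of 22 rose and 1 fell, with Plagl1 at 2.004 ± 0.19, adjusted p = 0.00012. The maternal-region imprinted median was 0.42 (adjusted p = 0.0038, and adjusted p = 0.22 with an estimated correlation). Maternal-region imprinted medians within slides 1 and 2 were 0.57 and 0.43. H19 (2.80 ± 0.18, adjusted p = 1.6e-05) and Mirg (1.89 ± 0.11, adjusted p = 1.2e-05) rose and Meg3 was not called (0.95 ± 0.15, adjusted p = 0.0013). The H19, Mirg and Meg3 median was 1.89 (adjusted p = 0.0042, and adjusted p = 0.2 with an estimated correlation). H19, Mirg and Meg3 medians within slides 1 and 2 were 2.06 and 1.72. Meg3 passed the fold threshold without WT Flk1+ replicate 1 or TKO Flk1+ replicate 2 (log2 1.03 and 1.13).

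Hypoxia and glycolysis genes fell: 1 of 20 rose and 15 fell, among them Pfkfb3 (-3.10 ± 0.08, adjusted p = 1.5e-07), the stress-response gene Ndrg1 (-3.28 ± 0.10, adjusted p = 3.8e-07), the TOR inhibitor gene Ddit4 (-2.59 ± 0.07, adjusted p = 1.6e-07) and the glucose transporter gene Slc2a3 (-2.10 ± 0.08, adjusted p = 1e-06). The hypoxia median was -1.84 (adjusted p = 2.5e-10, and adjusted p = 0.013 with an estimated correlation). Hypoxia medians within slides 1 and 2 were -1.70 and -1.94. Early mesoderm genes fell too: 1 of 29 rose and 12 fell, with the signalling gene Bmp4 at -2.59 ± 0.13, adjusted p = 4e-06, the forkhead gene Foxf1 at -2.996 ± 0.27, adjusted p = 9e-05 and the homeobox gene Msx2 at -1.67 ± 0.11, adjusted p = 2e-05. The early mesoderm median was -0.84 (adjusted p = 0.00026, and adjusted p = 0.027 with an estimated correlation). Early mesoderm medians within slides 1 and 2 were -0.90 and -0.68. Interferon-stimulated genes rose: 18 of 27 rose and 0 fell, with Parp14, Xaf1 and the RNA sensor gene Oas2 at least 10.2-fold, at least 8.2-fold and at least 8.43-fold higher. The interferon median was 2.31 (adjusted p = 9.7e-10, or 0.052 with an estimated correlation). It was 2.48 and 2.005 within slides 1 and 2, and 1.93 with genes at their bound. In p53 target genes 12 of 22 rose and 0 fell, with Ccng1 at 2.15 ± 0.11, adjusted p = 4.3e-06, Perp at 1.84 ± 0.10, adjusted p = 5.5e-06 and the antigen transporter gene Tap1 at 2.20 ± 0.10, adjusted p = 2.9e-06. The p53 target median was 1.11 (adjusted p = 2.2e-07, and adjusted p = 0.14 with an estimated correlation). P53 target medians within slides 1 and 2 were 0.96 and 1.29. Serum response genes included the matricellular gene Ccn1 (2.14 ± 0.11, adjusted p = 5.4e-06), and 8 of 21 rose and 4 fell (9 and 4 adjusted over the list alone). The serum response median was 0.83 (adjusted p = 0.0089, and adjusted p = 0.26 with an estimated correlation). Serum response medians within slides 1 and 2 were 0.82 and 0.64.

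Fibroblast and stromal genes were called higher in the same TKO Flk1+ samples as the interferon-stimulated genes: 5 of 29 rose and 0 fell, with the adhesion gene Vcam1 at least 3.26-fold (adjusted p = 0.0013) higher. Vcam1 was not called with normexp (log2 0.77). The stromal median was 0.84 (adjusted p = 0.04, or 0.52 with an estimated correlation), and 0.49 and 0.90 within slides 1 and 2. That call was lost without WT Flk1+ replicate 1, at 0.63 (adjusted p = 0.213), and without TKO Flk1+ replicate 2, at 0.28 (adjusted p = 0.107), and the adjusted p was 0.0523 to 0.274 (medians 0.28 to 0.84) over 4 alternatives that ended it. The collagen genes Col1a1 (-0.32 ± 0.29), Col1a2 (0.84 ± 0.33) and Col3a1 (1.005 ± 0.60) were not called. Not called as lists were blood and endothelial precursor genes (2 rose and 4 fell of 27, median -0.43, adjusted p = 0.4), in which the stem cell factor receptor gene Kit fell by 2.27 and Lmo2 by 1.60 on the log2 scale, and primitive red cell genes (2 rose and 1 fell of 10, median -0.32, mean 0.25, test direction down, adjusted p = 0.9), in which the embryonic globin gene Hbb-y rose (4.27 ± 0.25, adjusted p = 9.2e-06). Pluripotency (8 rose and 5 fell of 26, median 0.13, adjusted p = 0.56), primitive endoderm (5 rose and 3 fell of 21, median 0.29, adjusted p = 0.44), trophoblast stem cell (3 rose and 6 fell of 20, median -0.62, adjusted p = 0.21) and differentiated trophoblast genes (3 rose and 2 fell of 14, median -0.16, mean 0.68, test direction up, adjusted p = 0.52) were not called. Cell division (1 rose and 0 fell of 25, median 0.01, adjusted p = 0.74), sterol synthesis (0 rose and 2 fell of 24, median -0.03, mean -0.07, test direction up, adjusted p = 0.84), HOX (6 rose and 8 fell of 27, median -0.80, adjusted p = 0.44) and methylation machinery genes (2 rose and 5 fell of 15, median -0.32, adjusted p = 0.21) were not either. The X list, with its median and mean of opposite sign, was not called (178 rose and 60 fell of 988, median -0.09, mean 0.49, test direction up, adjusted p = 0.16).

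Neural precursor genes (7 rose and 2 fell of 14, median 0.85, adjusted p = 0.063) passed without WT Flk1+ replicate 1 (adjusted p = 0.0211, and 0.0165 to 0.0405 (medians 0.50 to 0.88) over 3 alternatives under which it passed). The endogenous retrovirus rule (3 rose and 0 fell of 12, median 0.52, adjusted p = 0.063) passed without WT Flk1+ replicate 2 or TKO Flk1+ replicate 1 (adjusted p = 0.021 and 0.0384, with 0.013 to 0.0384 (medians 0.41 to 0.60) over 4 alternatives under which it passed). Of the 13 lists called, 13 kept their call with slide and 13 with scan run as a block, and 3921 genes were called with slide as a block and 3644 with scan run as a block.

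The comparison of TKO with WT ntTS cells asks what changes in an extraembryonic stem cell. Among genes above background in both genotypes, the imprinted RNA H19 had the largest rise and the imprinted gene Grb10 the largest fall. H19 rose by 11.18 ± 0.18, adjusted p = 2.8e-08, and the RNAs Mirg and Meg3 of another imprinted cluster by 7.27 ± 0.11, adjusted p = 2.7e-08 and 6.52 ± 0.15, adjusted p = 1.1e-07. Grb10 (-7.29 ± 0.17, adjusted p = 1.3e-07) and Cdkn1c (-5.79 ± 0.13, adjusted p = 1.1e-07) fell, and Igf2 and Phlda2, a regulator of placental growth, were at least 671-fold (adjusted p = 5.6e-07) and at least 136-fold (adjusted p = 1e-08) lower and below background in TKO. On the X chromosome, Rhox2c (8.50 ± 0.29, adjusted p = 6.6e-07), Xlr3b (8.44 ± 0.19, adjusted p = 1.1e-07) and Fthl17f, a ferritin-like gene (7.52 ± 0.45, adjusted p = 1.3e-05), rose, and Rhox13 was at least 942-fold (adjusted p = 1.1e-07) higher. Rpl39l was at least 599-fold (adjusted p = 9.5e-06) higher, and the cartilage collagen gene Col2a1 fell (-6.28 ± 0.20, adjusted p = 4.6e-07). The trophoblast regulator genes Elf5 (-0.25 ± 0.34, adjusted p = 0.62) and Cdx2 (-0.59 ± 0.34, adjusted p = 0.23) were not called. Kdr (0.13 ± 0.10, adjusted p = 0.37) and Pou5f1 (-0.85 ± 0.26, adjusted p = 0.04), below background in TKO, did not pass either. Of 23837 genes 2920 were called, 1563 higher (505 below background in WT) and 1357 lower, or 3600 and 4518 with no minimum fold. Xist, the RNA that silences the inactive X, had 2 probes, of which 0 were well above background on both arrays of any group. TKO ES replicate 2 alone had 1 well above it. The RNA was cytoplasmic, so nuclear Xist was not tested.

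Germline genes rose: 33 of 50 rose and 3 fell, with the meiotic genes Fkbp6 and Syce1 at least 32.2-fold and at least 48.5-fold higher. The germline median was 1.72 (adjusted p = 5e-13, and adjusted p = 0.017 with an estimated correlation). Germline genes within 1 scan run had a median of 1.71, and 1.30 with genes at their bound. X-linked MAGE, Xlr and related genes rose: 19 of 28 rose and 0 fell, with Xlr4a at least 236-fold (adjusted p = 3e-05) higher. The MAGE and Xlr median was 3.69 (adjusted p = 9.9e-12, and adjusted p = 0.017 with an estimated correlation). MAGE and Xlr genes within 1 scan run had a median of 3.06, and 1.84 with genes at their bound. In the Rhox homeobox cluster 11 of 18 rose and 3 fell. The Rhox median was 2.02 (adjusted p = 0.00013, and adjusted p = 0.14 with an estimated correlation). Rhox genes within 1 scan run had a median of 1.92, and 1.90 with genes at their bound. Over probes well above background on all 12 arrays the Rhox median turned to -0.15 (adjusted p = 0.71). Under the same filter the MAGE and Xlr call was lost, at 0.94 (adjusted p = 0.0553). On the X chromosome 192 of 988 rose and 35 fell (193 and 35 adjusted over the list alone). The X-linked median was 0.05 (adjusted p = 0.0038, or 0.0093 with an estimated correlation). It was 0.04 within 1 scan run and 0.00 with genes at their bound. With no filter the X-linked median turned to -0.10 (adjusted p = 0.0265), with the test still directed upward, and over probes well above background on all 12 arrays the call was lost, at 0.005 (adjusted p = 0.146). H19, Mirg and Meg3 all rose. The H19, Mirg and Meg3 median was 7.27 (adjusted p = 5.3e-06, and adjusted p = 0.078 with an estimated correlation). H19, Mirg and Meg3 genes within 1 scan run had a median of 7.34. Imprinted genes next to a maternally methylated region rose: 8 of 22 rose and 1 fell, with the splicing factor gene Snrpn at 4.59 ± 0.11, adjusted p = 1.5e-07. The maternal-region imprinted median was 0.61 (adjusted p = 4.5e-05, and adjusted p = 0.13 with an estimated correlation). Maternal-region imprinted genes within 1 scan run had a median of 0.65. Those repressed when the control region is unmethylated fell: 2 of 21 rose and 8 fell. The repressed imprinted median was -0.46 (adjusted p = 0.0052, and adjusted p = 0.13 with an estimated correlation). Repressed imprinted genes within 1 scan run had a median of -0.64. Over probes well above background on all 12 arrays this call was lost, at -0.24 (adjusted p = 0.641).

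Interferon-stimulated genes rose in ntTS cells: 11 of 27 rose and 0 fell, with Xaf1 at 2.41 ± 0.15, adjusted p = 1.3e-05 and the RNA sensor gene Oas3 at least 5.98-fold (adjusted p = 0.00017) higher. The interferon median was 1.17 (adjusted p = 4.5e-05, and adjusted p = 0.14 with an estimated correlation). Interferon genes within 1 scan run had a median of 1.08, and 0.78 with genes at their bound. In p53 target genes 2 of 22 rose and 0 fell, with Ddit4l at 2.09 ± 0.12, adjusted p = 1.2e-05 and Cdkn1a at 1.43 ± 0.14, adjusted p = 0.00018. The p53 target median was 0.40 (adjusted p = 0.00031, and adjusted p = 0.24 with an estimated correlation). P53 target genes within 1 scan run had a median of 0.40. Early mesoderm genes fell: 0 of 29 rose and 8 fell (0 and 9 adjusted over the list alone), with Tbx3 at -2.84 ± 0.10, adjusted p = 6.6e-07 and Gata6 at least 36-fold (adjusted p = 8.4e-07) lower. The early mesoderm median was -0.81 (adjusted p = 5e-05, and adjusted p = 0.017 with an estimated correlation). Early mesoderm genes within 1 scan run had a median of -0.81, and -0.76 with genes at their bound. Blood and endothelial precursor genes fell: 2 of 27 rose and 8 fell, with Etv2 at -2.12 ± 0.15, adjusted p = 2.7e-05. The blood and endothelial median was -0.52 (adjusted p = 0.028, and adjusted p = 0.49 with an estimated correlation). Blood and endothelial genes within 1 scan run had a median of -0.64, and 0.00 with genes at their bound. Of differentiated trophoblast genes, 7 of 14 rose and 1 fell, including the pregnancy glycoprotein gene Psg23 (4.59 ± 0.12, adjusted p = 1.9e-07) among the rises and Igf2 as the fall. The differentiated trophoblast median was 1.01 (adjusted p = 0.028, and adjusted p = 0.15 with an estimated correlation). Differentiated trophoblast genes within 1 scan run had a median of 1.33, and 0.56 with genes at their bound. With no filter the differentiated trophoblast median turned to -0.15 (adjusted p = 0.113), and over probes well above background on all 12 arrays it was 0.015 (adjusted p = 0.121). For HOX genes, 2 of 27 rose and 7 fell, with Hoxa7 at -2.60 ± 0.13, adjusted p = 5.5e-06. The HOX median was -0.64 (adjusted p = 0.044, and adjusted p = 0.49 with an estimated correlation). HOX genes within 1 scan run had a median of -0.67, and -0.21 with genes at their bound. Cell division genes shifted with no member called. The cell division median was -0.23 (adjusted p = 0.044, and adjusted p = 0.14 with an estimated correlation). Cell division genes within 1 scan run had a median of -0.21. For the methylation machinery, 1 of 15 rose and 4 fell, with the demethylation enzyme gene Tet1 at -1.39 ± 0.17, adjusted p = 0.00056. Here too any deleted gene in the list is lower by design. The list median was -0.38 (adjusted p = 0.046, or 0.14 with an estimated correlation). It was -0.41 within 1 scan run and -0.37 with genes at their bound.

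Without WT ntTS replicate 2 the blood, trophoblast, HOX, cell division and methylation machinery lists were not called (adjusted p = 0.0898, 0.0557, 0.0898, 0.0901 and 0.0694), and without TKO ntTS replicate 1 the last 3 of these were not (adjusted p = 0.0644, 0.0597 and 0.052). Leaving out TKO ntTS replicate 2 ended the cell division call (adjusted p = 0.0569), and leaving out WT ES replicate 1 or 2 or WT Flk1+ replicate 1 or 2 ended the methylation machinery call (adjusted p = 0.0505, 0.0505, 0.0913 and 0.0913). Over every alternative that ended a call, the adjusted p was 0.0515 to 0.278 (medians -0.39 to -0.14) over 5 alternatives for blood, 0.0557 to 0.121 (medians -0.15 to 1.01) over 6 for differentiated trophoblast and 0.0507 to 0.0898 (medians -1.72 to -0.51) over 6 for HOX genes. It was 0.0569 to 0.104 (medians -0.24 to -0.15) over 10 for cell division and 0.0505 to 0.185 (medians -0.40 to -0.28) over 11 for methylation machinery genes. Trophoblast stem cell genes were not called (2 rose and 3 fell of 20, median -0.09, adjusted p = 0.42), although Esx1, a placental homeobox gene (-3.68 ± 0.42, adjusted p = 0.00038), and Krt8 (-1.45 ± 0.11, adjusted p = 4.7e-05) fell. Hypoxia (1 rose and 0 fell of 20, median -0.07, adjusted p = 0.89), pluripotency (2 rose and 6 fell of 26, median -0.36, adjusted p = 0.11), 2-cell stage (0 rose and 0 fell of 17, median -0.34, adjusted p = 0.81) and sterol synthesis genes (0 rose and 1 fell of 24, median -0.20, adjusted p = 0.14) were not called. Primitive endoderm (3 rose and 8 fell of 21, median -0.40, adjusted p = 0.1), neural precursor (1 rose and 3 fell of 14, median -0.50, adjusted p = 0.22) and serum response genes (1 rose and 3 fell of 21, median -0.08, adjusted p = 0.5) were not either. Primitive red cell genes (0 rose and 2 fell of 10, median -0.50, adjusted p = 0.11) passed without TKO ntTS replicate 2 (adjusted p = 0.0443, and 0.0443 to 0.0458 (medians -0.69 to -0.50) over 2 alternatives), and the endogenous retrovirus rule did not pass (2 rose and 0 fell of 12, median 0.07, adjusted p = 0.22). Fibroblast and stromal genes, markers of the feeder cells, were not called (0 rose and 3 fell of 29, median -0.06, adjusted p = 0.9), and Thy1 fell (-2.01 ± 0.12) in the samples in which the interferon-stimulated genes rose. All ntTS arrays were on 1 slide and WT ntTS replicate 1 was scanned in a run of its own, so within 1 scan run 1 WT array is compared with 2 TKO arrays.

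**Figure D2:**
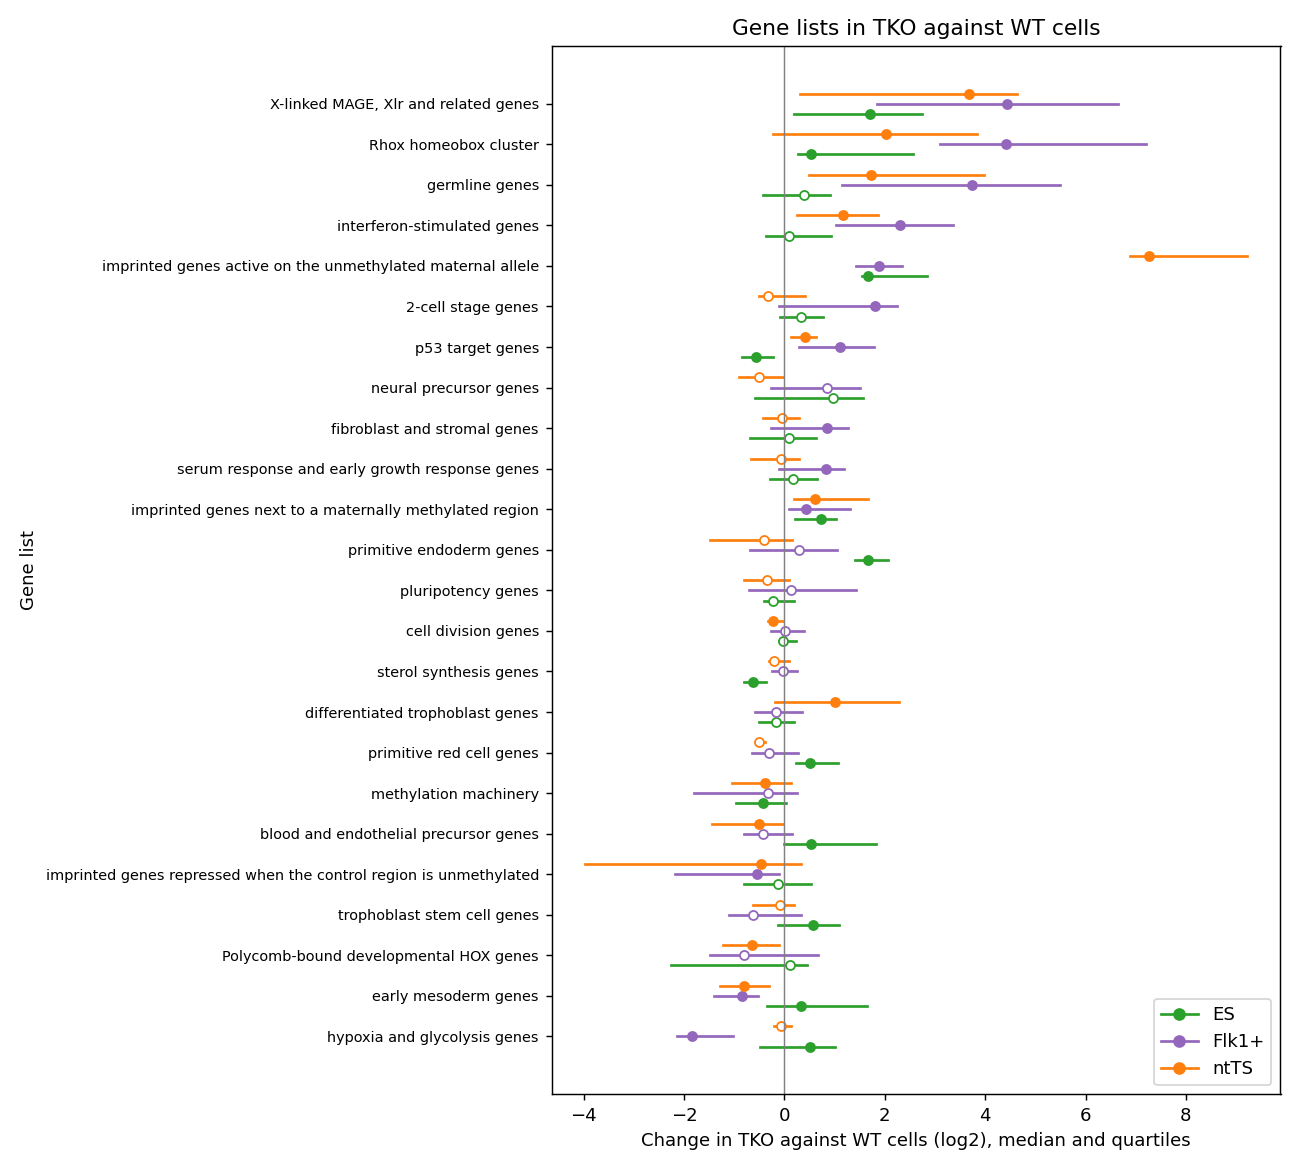
Median change (points) and quartiles (lines) of the 24 hand-written lists in TKO against WT cells (log2), for ES, Flk1+ and ntTS cells. Filled points are lists called by the set test: germline genes are at 0.39 in ES, 3.74 in Flk1+ and 1.72 in ntTS cells, and hypoxia and glycolysis genes at 0.51, -1.84 and -0.07.

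Testing the difference between TKO effects directly asks whether the contrast of TKO with WT differs between cell types. In ES cells that contrast also holds the difference in medium. Differences against ES cells thus cannot separate cell type from medium, for any list or gene given here. Germline genes rose more in Flk1+ than in ES cells, with a median difference of 2.83 (adjusted p = 2.9e-14, and adjusted p = 0.021 with an estimated correlation). The rise was also larger in ntTS than in ES cells, by 1.49 (adjusted p = 2e-08, and adjusted p = 0.051 with an estimated correlation). Between ntTS and Flk1+ cells the difference was -0.89 (adjusted p = 4.3e-05, and adjusted p = 0.18 with an estimated correlation). Primitive endoderm genes differed the other way, by -1.58 (adjusted p = 0.0033, and adjusted p = 0.08 with an estimated correlation) for Flk1+ minus ES. The primitive endoderm difference was -1.74 (adjusted p = 2e-07, and adjusted p = 0.021 with an estimated correlation) for ntTS minus ES. Hypoxia and glycolysis genes differed by -1.95 (adjusted p = 3.9e-11, and adjusted p = 0.011 with an estimated correlation) for Flk1+ minus ES. For ntTS minus Flk1+ the hypoxia difference was 1.68 (adjusted p = 1.1e-09, and adjusted p = 0.014 with an estimated correlation). Early mesoderm genes differed by -1.45 (adjusted p = 0.00032, and adjusted p = 0.038 with an estimated correlation) for Flk1+ minus ES, a call lost over probes well above background on all 12 arrays, at -0.78 (adjusted p = 0.0652). The mesoderm difference was -1.32 (adjusted p = 6.2e-05, and adjusted p = 0.032 with an estimated correlation) for ntTS minus ES. The p53 target genes, lower in TKO ES and higher in TKO Flk1+ cells, differed by 1.57 (adjusted p = 1.7e-09, and adjusted p = 0.12 with an estimated correlation). Interferon-stimulated genes differed by 1.91 (adjusted p = 1.9e-06, and adjusted p = 0.12 with an estimated correlation) between the same cells. Sterol synthesis genes differed by 0.53 (adjusted p = 0.00077, and adjusted p = 0.45 with an estimated correlation) for Flk1+ minus ES. The H19, Mirg and Meg3 list differed by 5.61 (adjusted p = 6.2e-05, and adjusted p = 0.12 with an estimated correlation) for ntTS minus ES, with H19 alone at 7.14 ± 0.26. By gene, 5067 differences passed for Flk1+ minus ES, 4295 for ntTS minus ES and 4699 for ntTS minus Flk1+.

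Some genes rose in TKO cells of more than 1 type. Of the higher genes, 504 were shared by ES and Flk1+ cells (159 with independence), 319 by ES and ntTS cells (104), 699 by Flk1+ and ntTS cells (156) and 204 by all 3 (10.4). Of the lower genes, 114, 153 and 225 were shared by the same pairs (78.2, 69.5 and 86.9 with independence) and 26 by all 3 (4.45). With a replicate block, which is a slide block here, 71 lower genes were shared by ES and Flk1+ cells (56.3 with independence). Genes called in opposite directions numbered 426, 423 and 287 for the same pairs (224, 171 and 235 with independence), so opposite calls also lay above independence. Across genes, which are not independent replicates, the fold changes correlated at r = 0.14, 0.06 and 0.36. X-linked genes made up 7.69% of higher genes in ES, 7.57% in Flk1+ and 12.4% in ntTS cells, against 4.17% of genes tested (Fisher's exact test, 2-sided, p = 5.8e-11, 2.1e-15 and 3.2e-44). Of the 204 genes higher in all 3 cell types, 39 of 199 with a chromosome were X-linked (19.6%, Fisher's exact test, p = 4.9e-16), among them Rhox2e, Rhox2h and Mageb4. Neighbouring X-linked gene families share sequence, so their probes are not independent counts.

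The comparison of Flk1+ with ES cells asks how differentiation to mesoderm proceeded in each genotype. The ES cells compared were in a different medium in each genotype. In WT cells, Cyp26a1, a retinoic acid-degrading enzyme gene (9.77 ± 0.18, adjusted p = 1.2e-08), Asb4 (9.73 ± 0.30, adjusted p = 8.2e-08) and the Wnt inhibitor gene Dkk1 (8.57 ± 0.21, adjusted p = 3e-08) rose, and the pluripotency-linked genes Zfp42 (-9.09 ± 0.73, adjusted p = 1.4e-05), Fbxo15 (-9.03 ± 0.08, adjusted p = 1.9e-09) and Tdh (-8.74 ± 0.48, adjusted p = 1.5e-06) fell. In TKO cells, Asb4 (9.85 ± 0.30, adjusted p = 1.5e-07), the homeobox gene Six2 (7.62 ± 0.16, adjusted p = 5.2e-08) and the Wnt agonist gene Rspo3 (7.56 ± 0.61, adjusted p = 2e-05) rose, and Tdh (-8.13 ± 0.48, adjusted p = 3.4e-06) and Fgf4 (-7.82 ± 0.39, adjusted p = 1.5e-06) fell. Of the early mesoderm genes, 28 of 29 rose and 0 fell in WT, and 28 of 29 rose and 0 fell in TKO. The early mesoderm median was 7.07, or 6.76 with genes at their bound, in WT (adjusted p = 1.9e-13, and adjusted p = 0.0031 with an estimated correlation). It was 4.61, or 4.45 with genes at their bound, in TKO (adjusted p = 4.4e-15, and adjusted p = 0.0022 with an estimated correlation). Pluripotency genes fell in both: 1 of 26 rose and 21 fell in WT and 1 of 26 rose and 20 fell in TKO. The pluripotency median was -4.93 in WT (adjusted p = 1.9e-07, and adjusted p = 0.17 with an estimated correlation). It was -4.78 in TKO (adjusted p = 5.3e-10, and adjusted p = 0.18 with an estimated correlation). In all, 8242 genes were called in WT (3804 higher) and 6791 in TKO (3181 higher).

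Other lists were called in WT and not in TKO cells, and the tests of those differences are the Flk1+ minus ES values above. Germline genes fell in WT: 1 of 50 rose and 42 fell. In TKO cells 10 of 50 rose and 19 fell, and the list was not called. The germline median was -3.72, or -2.97 with genes at their bound, in WT (adjusted p = 3.9e-13, and adjusted p = 0.019 with an estimated correlation). It was -0.42, or -0.36 with genes at their bound, in TKO (adjusted p = 0.18, and adjusted p = 0.49 with an estimated correlation). Hypoxia and glycolysis genes rose in WT. The hypoxia median was 2.15 in WT (adjusted p = 1.9e-07, and adjusted p = 0.018 with an estimated correlation). It was 0.30 in TKO (adjusted p = 0.18, and adjusted p = 0.29 with an estimated correlation). The p53 target genes fell in WT. The p53 target median was -1.59 in WT (adjusted p = 1.9e-07, and adjusted p = 0.14 with an estimated correlation). It was -0.21 in TKO (adjusted p = 0.78, and adjusted p = 0.96 with an estimated correlation). Interferon-stimulated genes fell in WT. The interferon median was -1.11, or -1.002 with genes at their bound, in WT (adjusted p = 0.00084, and adjusted p = 0.18 with an estimated correlation). It was -0.09 in TKO (adjusted p = 0.84, and adjusted p = 0.96 with an estimated correlation).

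**Figure D3:**
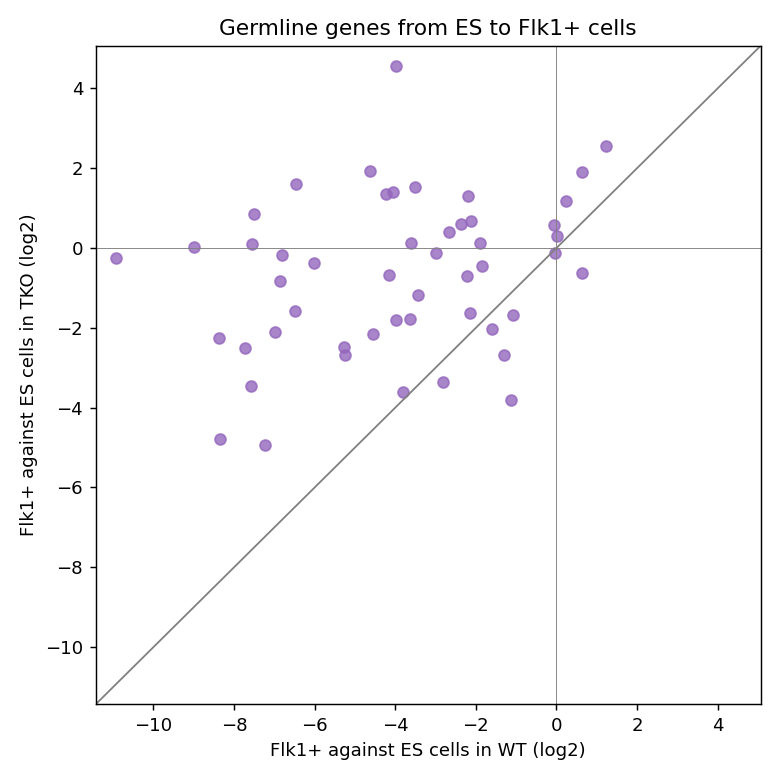
Change from ES to Flk1+ cells of each measured germline gene in WT (horizontal axis) and in TKO cells (vertical axis), log2, with the line of equal change. In WT 42 of 50 genes fell, against 19 in TKO cells, and points above the line fell less or rose more in TKO.

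The comparison of ntTS with ES cells sets the extraembryonic against the embryonic stem cell. In WT cells, Bmp8b, a signalling gene (9.18 ± 0.11, adjusted p = 4.3e-09), Rhox4e (8.45 ± 0.27, adjusted p = 1.1e-07) and Rhox4a (8.09 ± 0.18, adjusted p = 2.7e-08) were higher in ntTS cells, and the pluripotency genes Dppa5a (-11.44 ± 0.28, adjusted p = 3.5e-08), Fgf4 (-10.29 ± 0.39, adjusted p = 2.3e-07) and Pou5f1 (-9.89 ± 0.26, adjusted p = 4.7e-08) were lower. In TKO cells, the trophoblast regulator genes Hand1 (8.52 ± 0.37, adjusted p = 5.3e-07) and Cdx2 (8.51 ± 0.34, adjusted p = 3.4e-07) and Bmp8b (7.70 ± 0.11, adjusted p = 1e-08) were higher, and Dppa5a (-9.30 ± 0.28, adjusted p = 9.9e-08) and Nanog (-9.19 ± 0.22, adjusted p = 4.9e-08) were lower. Of the trophoblast stem cell genes, 17 of 20 rose and 1 fell in WT, and 17 of 20 rose and 2 fell in TKO. The trophoblast stem cell median was 4.14 in WT (adjusted p = 1.1e-07, and adjusted p = 0.045 with an estimated correlation). It was 3.07 in TKO (adjusted p = 6.4e-07, and adjusted p = 0.18 with an estimated correlation). Germline genes were lower in ntTS cells of both genotypes: 1 of 50 rose and 39 fell (2 and 39 adjusted over the list alone) in WT and 4 of 50 rose and 29 fell in TKO. The germline median was -3.32, or -2.68 with genes at their bound, in WT (adjusted p = 8.3e-12, and adjusted p = 0.034 with an estimated correlation). It was -1.11, or -1.09 with genes at their bound, in TKO (adjusted p = 0.00038, and adjusted p = 0.18 with an estimated correlation). The TKO value turned to 0.078 (adjusted p = 0.913) over probes well above background on all 12 arrays. The H19, Mirg and Meg3 list was lower in WT ntTS cells and not called in TKO. The H19, Mirg and Meg3 median was -6.57 in WT (adjusted p = 0.0049, and adjusted p = 0.18 with an estimated correlation). It was -0.96 in TKO (adjusted p = 0.66, and adjusted p = 0.81 with an estimated correlation). Its mean in TKO, of opposite sign, was 0.54. In all, 7546 genes were called in WT (3301 higher) and 7539 in TKO (3316 higher). Of 26 lists, 19 and 10 were called for Flk1+ against ES in WT and TKO cells, and 14 and 10 for ntTS against ES, of which 3, 1, 4 and 0 were called with an estimated correlation.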

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

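The tests of these patterns were chosen after the results were seen, apart from the scan-run test in ntTS cells and the test of a general lag, which were written before. Effects of the TKO genotype that differ between cell types are listed here because a test of the difference itself passed. Values are log2 differences of effects, and the effect in each cell type is in the results above.

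For Flk1+ minus ES, 5067 genes differed. More positive Flk1+ minus ES differences were those of the lists germline genes (2.83), Rhox homeobox cluster (2.69), X-linked MAGE, Xlr and related genes (3.17), interferon-stimulated genes (1.91), p53 target genes (1.57) and sterol synthesis genes (0.53). More negative Flk1+ minus ES differences were those of the lists imprinted genes repressed when the control region is unmethylated (-0.46), trophoblast stem cell genes (-0.74), early mesoderm genes (-1.45), blood and endothelial precursor genes (-1.06), primitive endoderm genes (-1.58) and hypoxia and glycolysis genes (-1.95). Of these 12 list differences 3 passed with an estimated correlation: germline genes (adjusted p = 0.021), early mesoderm genes (adjusted p = 0.038) and hypoxia and glycolysis genes (adjusted p = 0.011). The other 9 were lost, with an adjusted p of 0.08 to 0.45. Other alternatives ended the calls of these lists, with differences of MAGE and Xlr (-0.26), repressed imprinted (-0.46 to -0.26), early mesoderm (-0.78), blood and endothelial (-0.74) and trophoblast stem cell (-1.13 to -0.71) and adjusted p of 0.0501 to 0.426. More positive among named genes were Dnmt3b (1.10), Fbxo15 (1.96), Mageb4 (4.68), Psg23 (4.74), Rhox2e (6.43), Rhox2h (6.49) and Tuba3b (6.55). More negative among named genes were Cdx2 (-2.23), Ddit4 (-1.73), Foxa1 (-1.80), Gata3 (-4.23), H19 (-1.24), Igf2 (-3.82), Pfkfb3 (-4.30) and Slc2a3 (-3.10).

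For ntTS minus ES, 4295 genes differed. More positive ntTS minus ES differences were those of the lists germline genes (1.49), Rhox homeobox cluster (1.60), X-linked MAGE, Xlr and related genes (1.17), imprinted genes active on the unmethylated maternal allele (5.61), interferon-stimulated genes (0.50), p53 target genes (0.86) and sterol synthesis genes (0.39). More negative ntTS minus ES differences were those of the lists imprinted genes repressed when the control region is unmethylated (-0.48), early mesoderm genes (-1.32), blood and endothelial precursor genes (-0.89), primitive red cell genes (-0.96), primitive endoderm genes (-1.74) and cell division genes (-0.28). Of these 13 list differences 2 passed with an estimated correlation: early mesoderm genes (adjusted p = 0.032) and primitive endoderm genes (adjusted p = 0.021). The other 11 were lost, with an adjusted p of 0.051 to 0.45. Other alternatives ended the calls of these lists, with differences of red cell (-0.15), cell division (-0.28 to -0.21), Rhox (0.13), MAGE and Xlr (0.12), repressed imprinted (0.025), interferon (0.47 to 0.48) and sterol (0.36) and adjusted p of 0.0517 to 0.821. More positive among named genes were Cdkn1a (2.59), Dnmt1 (1.06), H19 (7.14), Meg3 (5.10), Mirg (5.61), Msmo1 (1.89), Psg23 (3.77), Rhox2e (4.27), Rhox2h (4.30), Snrpn (3.001) and Tuba3b (5.87). More negative among named genes were Epor (-5.42), Etv2 (-3.90), Foxa1 (-5.87), Igf2 (-7.34), Krt8 (-2.85), Pfkfb3 (-1.92) and Tbx3 (-1.54).

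For ntTS minus Flk1+, 4699 genes differed. More positive ntTS minus Flk1+ differences were those of the lists imprinted genes active on the unmethylated maternal allele (5.57) and hypoxia and glycolysis genes (1.68). More negative ntTS minus Flk1+ differences were those of the lists germline genes (-0.89), Rhox homeobox cluster (-1.41), 2-cell stage genes (-1.68), primitive endoderm genes (-1.14), fibroblast and stromal genes (-1.12), interferon-stimulated genes (-1.37) and p53 target genes (-0.34). Of these 9 list differences 1 passed with an estimated correlation: hypoxia and glycolysis genes (adjusted p = 0.014). The other 8 were lost, with an adjusted p of 0.18 to 0.53. Other alternatives ended the calls of these lists, with differences of primitive endoderm (-0.34 to -0.24), p53 target (-0.28 to -0.15), 2-cell stage (-1.16 to 0.65), stromal (-0.90 to -0.63) and interferon (-0.52) and adjusted p of 0.0504 to 0.546. More positive among named genes were H19 (8.38), Meg3 (5.57), Mirg (5.38), Pfkfb3 (2.38), Rhox13 (2.61) and Slc2a3 (3.49). More negative among named genes were Cdkn1c (-1.96), Foxa1 (-4.07), Grb10 (-1.54), Igf2 (-3.52), Oas2 (-2.99), Perp (-1.15), Rhox2e (-2.15), Rhox2h (-2.20), Thy1 (-1.26), Xaf1 (-2.76), Xlr3b (-1.37) and Xlr5b (-4.31).

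Sterol synthesis genes were lower in TKO ES cells, whose medium held serum where that of WT ES cells held serum replacement. A slide effect is argued against by the within-slide medians, -0.63 and -0.62. The TKO effect in Flk1+ cells, in 1 medium for both genotypes, differed from that in ES cells by 0.53 (camera adjusted p = 0.00077), and the list was not called in Flk1+ or ntTS cells. With an estimated correlation neither that difference (adjusted p = 0.45) nor the call in ES cells (adjusted p = 0.22) passed. The medium is thus a candidate explanation on the preset correlation only. Genotype and cell line stay open, since both differ with the medium in ES cells.

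Interferon-stimulated genes were higher in TKO Flk1+ and TKO ntTS cells at the preset correlation, and neither call passed with an estimated one (adjusted p = 0.052 and 0.14). The within-slide medians in Flk1+ cells (2.48 and 2.005) argue against slide, and the median over the ntTS arrays of 1 scan run (1.08, against 1.17 pooled) against scan run. Medians with genes at their bound were 1.93 in Flk1+ and 0.78 in ntTS cells, which argues against signals below background as the cause. The fibroblast and stromal median of -0.057 (SE 0.22) gave no sign of feeder cells, removed by a sort, in ntTS cells. This SE, like the next, is across genes, which are not independent. In Flk1+ cells, sorted from a stromal layer, that median was 0.84 (SE 0.20), but 0.28 without TKO Flk1+ replicate 2. Its call was lost with an estimated correlation (adjusted p = 0.52). Single stromal genes went both ways there. Col1a1 (-0.32), Thy1 (-0.75) and Postn (-0.20) lay below 0 and Col1a2 (0.84), Col3a1 (1.005) and Sparc (0.31) above it. None of these was called, Vcam1, below background in WT, was called higher, and Dcn was below background in both genotypes. Stromal cells and a response to the genotype thus cannot be told apart in Flk1+ cells.

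Hypoxia and glycolysis genes were lower in TKO Flk1+ cells, and rose from ES to Flk1+ cells in WT. The within-slide medians, -1.70 and -1.94, argue against slide and scan run. A general lag of differentiation stays open. Over 3787 other genes that rose in WT, the median TKO effect over WT rise was -0.25, against -0.65 for the 17 list members. The WT Flk1+ arrays both choose these genes and enter the ratio, which pulls it below 0 without any lag. With the genotypes exchanged, a comparison chosen after the results were seen, the ratio was -0.096 over 3177 other genes that rose in TKO, so the test does not decide. Cell density and oxygen, which the labels do not give, were not tested.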

How the results depend on the processing

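Scan run as a block was chosen after the data were seen. Counts are given in the order TKO against WT in ES, Flk1+ and ntTS cells, Flk1+ against ES in WT and TKO, ntTS against ES in WT and TKO, and the differences Flk1+ minus ES, ntTS minus ES and ntTS minus Flk1+. Overlaps are given as higher in ES and Flk1+, ES and ntTS, Flk1+ and ntTS and all 3, then lower in the same order. Counts of called genes stayed within 1.5 times the reported count under quantile normalization, median centring, no filter, the authors' value table, only the arrays compared, slide and scan run as blocks, the mean of probes, and moderation with trend and robust.

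With normexp background correction and quantile normalization the counts fell to 1255, 1858, 1228, 5153, 4057, 4498, 4414, 2913, 2393 and 2621 genes, and overlaps of 208, 139, 300, 89, 28, 30, 65 and 6. The cause was not tested.

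With only probes well above background on all 12 arrays the counts were 1247, 1940, 1367, 4604, 3534, 4165, 4140, 2839, 2346 and 2767 genes, and overlaps of 178, 135, 234, 76, 60, 60, 133 and 15. This filter drops genes below background in a group, so fewer genes are tested. Under it the X-linked MAGE and Xlr median turned to -0.25 in TKO Flk1+ cells, 0.35 for Flk1+ against ES in WT and -0.26 for the difference Flk1+ minus ES. The 2-cell stage median turned to -0.18 in TKO Flk1+ cells and 0.65 for ntTS minus Flk1+. The Rhox median turned to -0.15 in TKO ntTS cells and the X-linked median to -0.013 in TKO ES cells. In TKO, ntTS against ES, the germline median turned to 0.078 and the differentiated trophoblast median to -0.13. The median of imprinted genes repressed when the control region is unmethylated turned to 0.025 for ntTS minus ES. In ntTS cells 645 genes were higher and 722 lower in TKO, so the balance turned. It turned too for Flk1+ against ES in WT (2361 higher and 2243 lower) and TKO (1788 higher and 1746 lower), and for ntTS against ES in WT (2330 higher and 1835 lower) and TKO (2282 higher and 1858 lower). The differences Flk1+ minus ES (1389 higher and 1450 lower) and ntTS minus ES (1129 higher and 1217 lower) turned as well.

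Counts that stayed within 1.5 times could still turn their balance. For ntTS against ES in TKO they were 3737 higher and 3680 lower with quantile normalization, 3729 higher and 3696 lower with the authors' value table and 4087 higher and 3700 lower with median centring, and in WT 4175 higher and 3702 lower with median centring. For ntTS minus ES the reported balance was nearly even (2149 higher and 2146 lower) and turned under 10 alternatives in all.

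With no filter, the differentiated trophoblast median turned to -0.15 and the X-linked median to -0.10 in TKO ntTS cells.

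With no minimum fold, a looser rule by construction, the counts rose to 7562, 11871, 8118, 15528, 13037, 14321, 14193, 9974, 7873 and 9577 genes, and overlaps of 1295, 925, 1565, 502, 1299, 1152, 1627 and 447. The balance of TKO against WT calls turned, to 3478 higher and 4084 lower in ES, 5210 higher and 6661 lower in Flk1+ and 3600 higher and 4518 lower in ntTS cells. It also turned for Flk1+ against ES in WT (8002 higher and 7526 lower), Flk1+ minus ES (4959 higher and 5015 lower) and ntTS minus ES (3889 higher and 3984 lower).

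With a replicate block the overlap of lower genes in ES and Flk1+ cells was 71, against 56.3 with independence under that block. The other counts stayed within 1.5 times. In these cell types the replicate number is also the slide, and the block is fitted over the arrays compared alone. The cause was not tested.

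Leaving out 1 array gave 2446 to 2837 genes in ES, 3741 to 4024 in Flk1+ and 2690 to 2965 in ntTS cells. The group left with 1 array is assumed to vary like the others. Of list tests with a reported call or in a TKO contrast, 1934 of 1980 kept their side of the threshold on leaving out an array, 153 of 165 with normexp, 114 of 165 with the filter on all 12 arrays, 159 of 165 with slide as a block and 155 of 165 with scan run as a block. With an estimated correlation in camera, 105 of these 165 tests lost a call, and not all of the 165 had a call to lose. For TKO against WT in ES, Flk1+ and ntTS cells, that estimate kept 2 of 14, 4 of 13 and 4 of 15 list calls. Signal over background limits what can be called: 780 of 2376 higher genes in TKO Flk1+ cells were below background in WT and have only a lower bound.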

Other observations

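Features described in the array annotation as retroviral elements, other than host genes, are a set chosen after the values were seen and were not tested as a group. Of 13 such features, 10 were tested, and 6 rose in ES, 7 in Flk1+ and 7 in ntTS cells. None fell in the 3 cell types, 2 rose in none of them, and the endogenous retrovirus rule fixed beforehand was not called in any. The feature described as an intracisternal A-particle-related retroviral element rose by 2.67 ± 0.11 in ES cells and was at least 329.6-fold higher in Flk1+ and at least 715-fold higher in ntTS cells, below background in WT in the latter 2 cell types.

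Failed silencing of germline genes on differentiation was a hypothesis whose tests by share were written before the results were seen. Of 42 germline genes lower in WT Flk1+ than WT ES cells, 18 were also lower in TKO (42.9%), against 2604 of 4396 other genes (59.2%, Fisher's exact test, p = 0.04). Of 39 lower in WT ntTS cells, 26 were also lower in TKO (66.7%), against 2843 of 4206 others (67.6%, Fisher's exact test, p = 0.87). Their median changes, compared afterwards, were -4.10 in WT and -0.69 in TKO for Flk1+ and -3.88 and -1.65 for ntTS cells. A change in TKO is the change in WT plus the difference of TKO effects given above, so both tests restate that difference on genes chosen for a fall in WT. Whether silencing failed or the genes were switched on in TKO stays open in both cell types.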
